A study of Rattus norvegicus and Mus musculus with 39 samples.

How the data were processed

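The samples were testes of rats and mice given an oral dose of 700 mg/kg mono(2-ethylhexyl) phthalate (MEHP), the active metabolite of the plasticizer di(2-ethylhexyl) phthalate, or corn oil. The labels give day 2 as the time. Total RNA was extracted and 2000 ng per sample entered library construction for Tag-seq, which sequences a short tag of each transcript in place of its whole length. The 39 libraries fall into 6 groups. These are 7 adult rats on corn oil, 5 adult rats on MEHP, 7 peripubertal rats on corn oil, 7 peripubertal rats on MEHP, 7 peripubertal mice on corn oil and 6 peripubertal mice on MEHP. The ages were read from the sample names together with the study's description of its design. The labels speak of treated animals but do not state that each library came from a different one, so p-values measure the spread between these libraries.

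Per the submitters' processing notes, the processing used FastQC, Bowtie2, DESeq2 and DESeq, with the builds Rnor_6.0 for the rat and mm10 for the mouse. Versions, counting rules and strand settings are not given in the sources used here. The files used here are the authors' comparison tables, with 3 terms of a rat model (age, treatment and age by treatment) and 1 mouse comparison. In each, the base mean is a signal on the normalized count scale, averaged by the authors over all libraries of a species. The effect is the authors' deposited log2 fold change with its standard error (SE). The Wald statistic deposited by the authors is a score, the fold change divided by its SE. This was checked for every gene in the 3 rat terms, so the rat fold changes were not shrunken. The mouse comparison was not checked in this way. The deposited p-value and adjusted p-value are those of the authors' DESeq2 analysis. The authors also deposited gene ontology (GO) tables with the p-value of each term and lists of the genes of the 10 top terms of each of 3 ontologies. Values per library were not analysed here, so the depth of each library is unknown, and no count test, left-out library, replicate block or other split of the libraries could be computed.

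The rat tables list 21654 genes, of which 303 have a base mean of 0 and no estimate. The deposited adjusted p covers 16801 genes for the treatment term, 14319 for the age-by-treatment term and 19696 for the age term, as low base means were left without one. The mouse table lists 38090 genes, and 38081 have an adjusted p. Base means of at least 10 were reached by 13987 rat and 17743 mouse genes. The treatment term is the effect in adult rats, since the authors' GO statistics for adult rats equal it in 7209 matched genes. The age term is the difference among corn-oil rats, with corn oil as the reference named in the treatment table.

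The effect in peripubertal rats was derived as the treatment term plus the age-by-treatment term. Its variance is the squared SE of the age-by-treatment term minus that of the treatment term, because the peripubertal and adult contrasts share no library. A two-sided Wald test was adjusted by Benjamini-Hochberg (BH) over 21351 genes, and every one of these had a positive variance. In genes with a base mean of at least 200, the median ratio of peripubertal to adult SE was 0.870, against 0.913 from the group sizes alone with equal spread. The Wald test of the derived effect was run on simulated counts of 13987 genes. These had the group sizes, levels and spread of the rat data and a known dispersion. The derived effect there equals the direct peripubertal contrast by construction, so the simulation could not test the derivation. The Wald test recovered 99% of 100 genes changed by log2 1 and 72% of 100 genes changed by log2 0.5. Of the called genes, 2.29% were false. The dispersion was known there, so these rates do not cover its estimation in the rat data. Where a mean level per group is given, it was implied by the base mean and the model terms, and it is not a measured group mean.

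Genes were called at an adjusted p under 0.05, from the authors' table where it holds the comparison. Before the data were examined, 24 gene lists were fixed for testis cell types, pathways and stress responses. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the Wald statistic, two-sided, with a preset correlation between genes of 0.01 and BH over the 24 lists of a comparison. An estimated correlation needs values per library, so 0.05 was used as an alternative. On simulated statistics of 15000 unchanged genes, drawn independently of each other, 2.71% of 480 random lists of 20 genes passed an unadjusted 0.05. A shift of the statistic by 1 was found in 99.2% of 480 such lists. Correlated genes were not simulated, so these rates do not cover lists whose members move together. Members were matched by symbol, and 37134 of the mouse gene IDs (97.5%) were found in GENCODE M21, on the same assembly as mm10. The mouse table leaves the name of 2006 genes blank, and 1950 of them were named from GENCODE. Rat coordinates are not given, since the annotation used here is on another assembly.

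Named genes followed a rule fixed at the same time as the lists. It takes the 6 largest positive and 6 largest negative log2 fold changes among called genes with a base mean of at least 10 and an established symbol, or 4 and 4 for the age term. It adds the 3 members with the smallest adjusted p of each list with at least 3 called members or a set test past 0.05, for at most 8 lists per comparison (6 for age). If under 6 genes were called, all are named. The values of 3 genes that the rule selects are not reported here, and the counts include them. Rat and mouse genes were paired by identical symbol, ignoring case. The alternatives were other thresholds, a minimum log2 fold change of 1, other adjustments, a base mean minimum of 10, a t distribution with 22 degrees of freedom for the derived effect, and other settings of the list tests. These alternatives were planned. The naming of blank mouse genes from GENCODE, the test of the difference between the species, the comparison of GO rankings and the tests with the larger SE of each gene were chosen after the data were examined. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.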

Results

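Gene expression was measured by Tag-seq in whole testis of adult rats, peripubertal rats and peripubertal mice after an oral dose of 700 mg/kg MEHP or corn oil. The groups held 7 and 5 libraries (corn oil and MEHP) in adult rats, 7 and 7 in peripubertal rats, and 7 and 6 in peripubertal mice. Values are log2 fold changes of MEHP over corn oil with their SE. Those of adult rats, mice, the age-by-treatment term and the age term come from the authors' deposited tables, and those of peripubertal rats were derived from them. The depth of each library is unknown. The SEs therefore set the precision, with medians of 0.11 in adult rats, 0.09 in peripubertal rats and 0.09 in mice for genes with a base mean of at least 50.

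In adult rats, MEHP was followed mainly by higher expression. In the authors' deposited table, 137 genes were higher and 3 were lower, of 16801 tested. Among genes with a base mean of at least 10 and an established symbol, the largest rises in the authors' deposited table were in the signalling protein gene Wnt4 (4.63 ± 0.54 SE, adjusted p 4.4e-14), Calca (4.58 ± 1.09), which encodes calcitonin gene-related peptide, and the heme-binding protein gene Hpx (4.34 ± 0.66, adjusted p 1.67e-07). Testin, a protein secreted by Sertoli cells at their junctions with germ cells, rose by 3.63 ± 0.41 (adjusted p 8.64e-15), Hamp, which encodes the iron hormone hepcidin, by 3.59 ± 0.48, and the intermediate filament gene Nes by 3.18 ± 0.48 in the authors' deposited table. The 3 lower genes in the authors' deposited table were Lrrc36 (-0.31 ± 0.07), Ccdc188 (-0.29 ± 0.08) and Tmem131l (-0.27 ± 0.07), and the call of Ccdc188 was lost with BH over all genes (adjusted p 0.0591). The base mean of Calca was 10.1 in the authors' deposited table, so its fold change rests on low levels. Implied adult corn-oil levels were also low for Wnt4 (3.22), Hamp (3.57) and Nes (6.75), against 13.2 for Hpx and 14.5 for Testin.

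The macrophage and cytokine lists stood higher in the adult rats, with a minority of members called. Of 24 measured monocyte and macrophage markers, 4 were called higher and 0 lower (6 higher adjusted over the list alone), and the list stood above the other genes (adjusted p 6.06e-12, cameraPR). The complement genes C1qb and C1qc rose by 1.45 ± 0.26 and 1.03 ± 0.23, and the hemoglobin scavenger receptor gene Cd163 rose by 1.53 ± 0.30, in the authors' deposited table. Of 27 genes in the cytokine and chemokine inflammation list, 3 were called higher and 0 lower, and 6 higher adjusted over the list alone. Its set test gave an adjusted p of 1.06e-06 (cameraPR). The called genes in the authors' deposited table were Spp1 (1.83 ± 0.41), which encodes osteopontin, Socs3 (1.95 ± 0.52) and Icam1 (1.23 ± 0.33). Socs3 is a cytokine-signalling inhibitor gene and Icam1 an adhesion gene, so the list is not made of cytokines alone. Their base means in the authors' deposited table were 10.5 for Spp1, 10.2 for Socs3 and 13.8 for Icam1, so these fold changes rest on low levels.

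Lists of cytoskeleton, oxidative stress, metalloproteinase and immediate early genes also stood higher in the adult rats. The heat shock list (adjusted p 0.0878) and the integrated and endoplasmic reticulum stress list (0.776) did not pass. The cytoskeleton list had 2 of 18 members called higher (6 adjusted over the list alone; adjusted p 1.58e-05), namely Anxa2 (0.76 ± 0.17) and the tubulin gene Tubb3 (0.41 ± 0.10), while Tubb5 (0.36 ± 0.11, adjusted p 0.0729) did not pass, in the authors' deposited table. The oxidative stress list had 2 of 21 members called higher (4 adjusted over the list alone; adjusted p 6.94e-05), the peroxiredoxin gene Prdx1 (0.30 ± 0.07) and the heme oxygenase gene Hmox1 (0.40 ± 0.10), and Sod2 was at 0.25 ± 0.08 (adjusted p 0.119) in the authors' deposited table. Among 18 metalloproteinase genes and their inhibitors, Timp1 was the 1 called member (3 adjusted over the list alone; set test adjusted p 0.000889). Timp1 rose by 2.21 ± 0.35 in the authors' deposited table, where Adamts1 was at 1.42 ± 0.52 (adjusted p 0.301). Of 19 immediate early genes 1 was called (2 adjusted over the list alone; adjusted p 0.00388), the survival gene Ier3, and with ranks the list did not pass (adjusted p 0.0510). The authors' deposited table gave Ier3 at 1.36 ± 0.29, Klf6 at 0.55 ± 0.16 (adjusted p 0.0504; 0.0448 with BH over genes with a base mean of at least 10) and Jun at 0.50 ± 0.20 (adjusted p 0.412).

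Some lists of somatic cell markers stood higher in the adult rats, and spermatid lists stood lower with 0 called members. The Leydig cell (adjusted p 0.486), spermatocyte (0.0956) and spermatogonia (0.959) lists did not pass. Of 18 Sertoli cell markers 1 was called (3 higher and 1 lower adjusted over the list alone), and the list stood higher (adjusted p 0.00368). The cathepsin gene Ctsl rose by 0.68 ± 0.15 in the authors' deposited table, where Aard was at 0.22 ± 0.06 (adjusted p 0.0570) and Inhbb, an inhibin subunit gene, at -0.43 ± 0.14 (adjusted p 0.141). Of 10 peritubular myoid markers 1 was called, also when adjusted over the list alone, and the list stood higher (adjusted p 0.0013). The myosin gene Myl9 rose by 0.34 ± 0.09 in the authors' deposited table, with Des at 0.56 ± 0.26 (adjusted p 0.638) and Cnn1 at 0.38 ± 0.24 (adjusted p 0.826). The endothelial list (13 genes, adjusted p 0.00151) and the fibroblast and matrix list (16 genes, adjusted p 0.00456) stood higher with 0 called members, and adjusted over the list alone they had 0, and 4 higher and 1 lower. Round spermatid markers (18 genes, median -0.09, adjusted p 0.0284) and elongating spermatid markers (19 genes, median -0.12, adjusted p 0.0456) stood lower, with 0 called members and 0 adjusted over the list alone. The spermatid calls were lost with a correlation of 0.05 between genes (adjusted p 0.105 and 0.145) and among genes with a base mean of at least 10 (0.0830 and 0.111).

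In peripubertal rats, MEHP was followed mainly by higher expression, with a share of lower genes that depends on the setting. The derived effect called 515 genes higher and 298 lower of 21351, with a median absolute log2 fold change of 0.33 among called genes, against 0.84 among those called in adult rats in the authors' deposited table. Larger SEs in adult rats let fewer small changes pass, and whether they account for this gap was not tested. With a log2 fold change of at least 1, 67 genes were called in peripubertal rats (64 higher and 3 lower) and 59 in adult rats (all higher). Within the same limits on base mean and symbol, the largest derived rises were in Hpx (4.98 ± 0.62 SE, adjusted p 3.83e-12), Calca (4.46 ± 0.78), the neuropeptide precursor gene Vgf (3.91 ± 0.72), Testin (3.13 ± 0.36, adjusted p 1.03e-14), the cadherin gene Cdh17 (3.03 ± 0.38) and the protease inhibitor gene Serpinb1a (2.89 ± 0.42). The base mean is pooled over both ages, so it does not exclude low levels in the peripubertal rats. Implied peripubertal corn-oil levels were 4.95 for Hpx and 1.38 for Calca, against 19.9 for Testin. Vgf and Cdh17 had base means of 31.6 and 38.0 in the authors' deposited table. Their age terms there were -5.61 and -4.66, so their rises also started from low peripubertal levels. The largest derived falls within these limits were in Tnp2 (-5.57 ± 1.06, adjusted p 4.91e-05), a transition protein gene of condensing spermatids, the nicotinic receptor gene Chrna4 (-1.02 ± 0.24), the oxidase gene Hao2 (-0.86 ± 0.20), Dpysl4 (-0.78 ± 0.23), the betaine-homocysteine methyltransferase gene Bhmt (-0.74 ± 0.19) and Cesl1 (-0.70 ± 0.17). The SE of Tnp2 was the largest of 69 rat genes with base means of 5000 to 50000, whose median was 0.06. With a t distribution of 22 degrees of freedom in place of the normal one, 245 genes were called, 196 higher and 49 lower, and with Holm adjustment 92 were higher and 10 lower. Among the genes named for peripubertal rats here, the t distribution ended the calls of Dpysl4 (adjusted p 0.104), Bhmt (0.0647), Col4a1 (0.133), Mmp11 (0.117), Cd163 (0.131), Atf3 (0.0914) and Ptgds (0.0845).

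The Sertoli cell, junction and cytoskeleton lists stood higher in the peripubertal rats. Of 18 Sertoli cell markers, 7 were called higher and 0 lower (9 higher adjusted over the list alone; set test adjusted p 4e-08), among them Ctsl (1.15 ± 0.14), the hedgehog ligand gene Dhh (0.53 ± 0.11) and the tight junction gene Cldn11 (0.29 ± 0.07). Of 21 blood-testis barrier and junction genes, 8 were called higher and 0 lower (10 higher adjusted over the list alone; adjusted p 1.75e-06). These included the junctional adhesion gene F11r (0.49 ± 0.11) and the N-cadherin gene Cdh2 (0.53 ± 0.12). The cytoskeleton list had 7 of 18 members higher and 1 lower (12 and 2 adjusted over the list alone; adjusted p 1.75e-06), with Tuba1c (0.78 ± 0.17) and vimentin, Vim (0.48 ± 0.11), higher and Tubb4b (-0.18 ± 0.04) lower.

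The matrix, metalloproteinase and macrophage lists stood higher as well in the peripubertal rats, with a minority of members called. Of 16 fibroblast and matrix genes, 4 were called higher and 0 lower (9 higher adjusted over the list alone; set test adjusted p 4.3e-09), including Sparc (0.55 ± 0.10), Vim and the basement membrane collagen gene Col4a1 (0.64 ± 0.21). Of 18 metalloproteinase genes and inhibitors, 4 were called higher and 0 lower (4 adjusted over the list alone; adjusted p 7.07e-05), with Timp1 at 1.75 ± 0.31, the plasminogen activator gene Plat at 0.96 ± 0.22 and Mmp11 at 0.36 ± 0.11. Of 24 macrophage markers, 3 were called higher and 0 lower (5 adjusted over the list alone; adjusted p 3.91e-05, and 0.184 by a Fisher exact test of called members), namely the lysozyme gene Lyz2 (1.10 ± 0.24), Mpeg1 (0.46 ± 0.10) and Cd163 (0.91 ± 0.29). The immediate early list passed (19 genes, 2 called higher, 2 adjusted over the list alone, adjusted p 0.0382), but not with a correlation of 0.05 (adjusted p 0.149).

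Spermatocyte, stress and steroidogenic genes gave a different picture in the peripubertal rats. Of 26 spermatocyte markers, 2 were called lower and 0 higher (6 lower adjusted over the list alone), and the list stood lower (median -0.11, adjusted p 1.75e-06). The stress list of 19 genes did not pass the set test (adjusted p 0.0898), with 2 called lower and 1 higher (the same numbers adjusted over the list alone). They were Ddit3 (-0.30 ± 0.06), which encodes the transcription factor CHOP, Sdf2l1 (-0.26 ± 0.06) and the stress factor gene Atf3 (1.26 ± 0.36). The Leydig cell list of 20 genes did not pass either (adjusted p 0.665), with Tspo (0.61 ± 0.11), a mitochondrial protein gene of steroidogenic cells, and Ptgds (0.47 ± 0.13) higher and Hao2 lower (2 higher and 1 lower adjusted over the list alone).

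**Figure D1:**
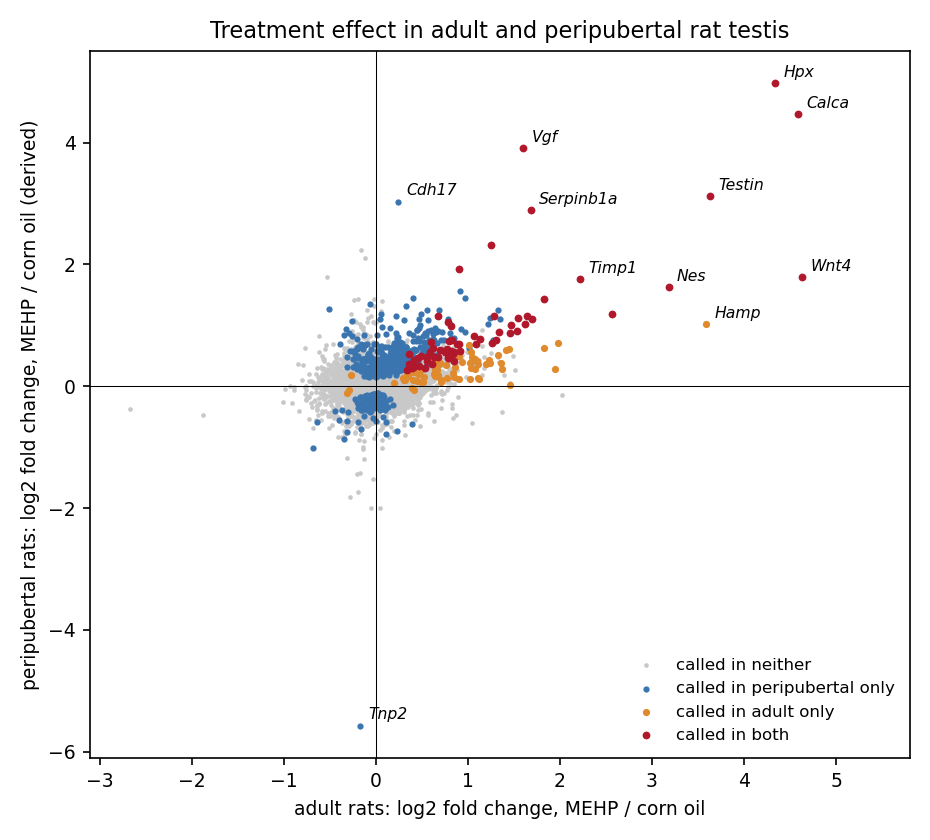
Each point is a rat gene with a base mean of at least 10, with its log2 fold change (MEHP over corn oil) in adult rats on the x axis and the derived one in peripubertal rats on the y axis, colored by the comparisons in which its adjusted p was under 0.05. Hpx and Calca lie above 4 on both axes, Cdh17 is at 0.24 and 3.03, and Tnp2 is at -0.17 and -5.57.

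The ages shared genes that rose. Among 16801 genes tested at both ages, 137 were called higher in adult and 515 in peripubertal rats, and 68 were in both lists, against 4.2 for independent lists (Fisher exact test, two-sided, 2.51e-66). Of the 140 genes called in adult rats, 137 had the same sign in peripubertal rats. Of the 813 genes called in peripubertal rats, 609 had the same sign in adult rats. No gene was called lower at both ages, where 3 and 298 were called and 0.0532 would be shared by independent lists. Across all 21351 genes the fold changes of the ages had a Spearman rho of 0.106, and genes are not independent replicates.

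The age-by-treatment term tests the difference between the ages itself. In the authors' deposited table it was past the threshold for 17 genes, 14 with a higher and 3 with a lower fold change in peripubertal than in adult rats, of 14319 tested. The largest positive differences in the authors' deposited table were in Cdh17 (2.79 ± 0.46, adjusted p 2.41e-05), the ubiquitin ligase adaptor gene Fbxo2 (1.77 ± 0.35), the adaptor gene Stap2 (1.41 ± 0.30), the secretin receptor gene Sctr (1.33 ± 0.28) and the thioesterase gene Them5 (1.19 ± 0.27). The 3 negative differences in the authors' deposited table were in Wnt4 (-2.84 ± 0.65), Hamp (-2.57 ± 0.58) and the glutathione transferase gene Gstp1 (-0.91 ± 0.21). Wnt4 was called in both ages, with a derived rise of 1.80 ± 0.37 in peripubertal rats. Hamp (1.02 ± 0.33, adjusted p 0.0529) and Gstp1 (0.12 ± 0.14, adjusted p 0.854) were not called in peripubertal rats, and Gstp1 rose by 1.03 ± 0.16 in adult rats in the authors' deposited table. Of the 14 genes with a positive difference, 13 were called in peripubertal rats and 1 in adult rats. Of the same 14 genes, 12 were called lower in peripubertal than in adult corn-oil rats, against 6552 of all 19696 genes tested for age in the authors' deposited table, and the other 2 were not called for age. Examples are implied corn-oil levels of 2.53 in peripubertal and 63.96 in adult rats for Cdh17, 6.22 and 111.5 for Stap2, and 6.21 and 117.9 for Sctr. The 3 genes with a negative difference were called higher in peripubertal than in adult corn-oil rats. Implied corn-oil levels were 51.82 in peripubertal and 3.22 in adult rats for Wnt4. They were 16.75 and 3.57 for Hamp, and 428.3 and 238.2 for Gstp1. The larger adult fold changes thus started from lower levels. With MEHP, Wnt4 stood at 180.1 in peripubertal and 79.8 in adult rats, while Hamp and Gstp1 stood higher in adult rats. The age term shares its corn-oil libraries with the age-by-treatment term, so these are not independent.

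Gene lists moved less clearly between the ages. The fibroblast and matrix list (adjusted p 0.0175), the Sertoli cell list (0.0279) and the junction list (0.0350) had higher fold changes in peripubertal rats, and the cytokine list (0.0175) and the spermatocyte list (0.0238) had lower ones. All of these were lost with a correlation of 0.05 (adjusted p at least 0.161). None of the 5 lists had a called member, and adjusted over the list alone 1 Sertoli, 1 spermatocyte and 0 other members passed. In the authors' deposited table the interleukin gene Il6 was at -0.58 (adjusted p 0.411), Socs3 at -1.66 (adjusted p 0.326), the collagen gene Col1a1 at 1.08 (adjusted p 0.514), the meiotic kinase gene Aurkc at -0.38 (adjusted p 0.198) and the nectin gene Nectin2 at 0.35 (adjusted p 0.440).

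In peripubertal mice, 1 of 38081 genes was past the threshold in the authors' deposited table. Serpina3n, an acute-phase protease inhibitor gene, rose by 2.25 ± 0.46 (adjusted p 0.0427) in the authors' deposited table. Its base mean was 8.31 there, and the implied levels were 3.03 in corn-oil and 14.5 in MEHP mice. The gene lies on chromosome 12 from 104406729 to 104414329 on the plus strand of mm10 (GENCODE M21, protein coding). In the authors' DESeq2 table, 862 mouse genes had an unadjusted p under 0.05, of 38081. The Serpina3n call was lost when genes under a base mean of 10 were left out, which removes the gene itself.

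**Figure D2:**
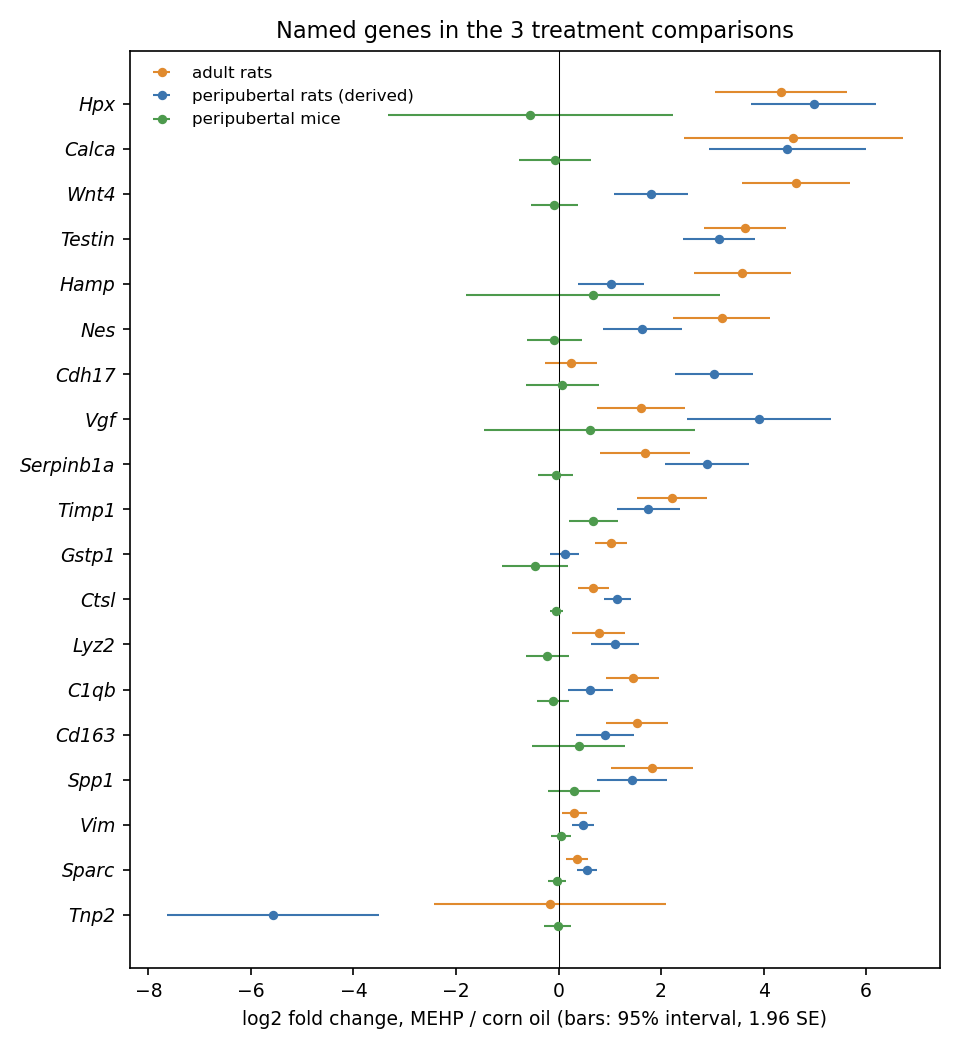
Log2 fold changes (MEHP over corn oil, x axis) of 19 named genes (y axis) in adult rats, peripubertal rats and peripubertal mice, with 95% intervals as bars. Hpx is at 4.34 and 4.98 in the rats and at -0.55 in the mice, where its base mean is 0.654, and Testin has no mouse value.

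Although 1 mouse gene was called, several lists stood lower together in the mice. All 11 lists past the set test stood lower and 0 stood higher. They span germ cell, somatic, immune and metabolic genes. With a correlation of 0.05 between genes, 6 passed, and these held germ cell, somatic and metabolic lists but not the macrophage list. The spermatocyte list (median -0.002) and the fibroblast and matrix list (median 0.04) did not pass in either setting. Among genes with a base mean of at least 10, 9 of the 11 passed. There the adjusted p (cameraPR) was 0.0001355 for the Leydig list and 0.0365 for the endothelial list. The Leydig cell and steroidogenesis list (21 genes, median -0.24, adjusted p 4.37e-07) had 0 called members and 0 adjusted over the list alone. The authors' deposited table gave the cholesterol transporter gene Star at -0.57 ± 0.22, the luteinizing hormone receptor gene Lhcgr at -0.46 ± 0.20 and the steroid hydroxylase gene Cyp17a1 at -0.77 ± 0.35, none past the threshold (adjusted p 0.997 for each). The cholesterol biosynthesis list (25 genes, median -0.11, adjusted p 2.12e-06) had 0 called members and 1 lower adjusted over the list alone, with Insig1 at -0.34 ± 0.10, Sc5d at -0.37 ± 0.14 and Srebf2 at -0.22 ± 0.10 in the authors' deposited table (adjusted p 0.997 for each). Round spermatid markers (20 genes, adjusted p 0.000732), peritubular myoid markers (10 genes, adjusted p 0.00152), endothelial markers (13 genes, adjusted p 0.00271) and the cytoskeleton list (21 genes, adjusted p 0.00271) also stood lower. Each of these had 0 called members, and adjusted over the list alone the myoid and cytoskeleton lists had 1 lower each. The authors' deposited table gave the myoid gene Mylk at -0.30 ± 0.09, the vascular receptor gene Kdr at -0.53 ± 0.21 and Anxa2 at -0.25 ± 0.07 (adjusted p 0.997 for each). The cytoskeleton list did not pass with ranks (adjusted p 0.108).

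Other mouse lists passed with a correlation of 0.01 and were lost with 0.05. They were the macrophage list (adjusted p 0.00642, then 0.0609), spermatogonia markers (0.0216, then 0.107), immediate early genes (0.0399, then 0.153), the junction list (0.0463, then 0.179) and the fatty acid oxidation list (0.0494, then 0.211). All had 0 called members, and adjusted over the list alone the macrophage and fatty acid oxidation lists had 1 lower each. Among genes with a base mean of at least 10, the junction (adjusted p 0.112, cameraPR) and immediate early (0.110) lists were lost as well. Cd74, the invariant chain gene of antigen presentation, was at -1.03 ± 0.27 (adjusted p 0.997) in the authors' deposited table.

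**Figure D3:**
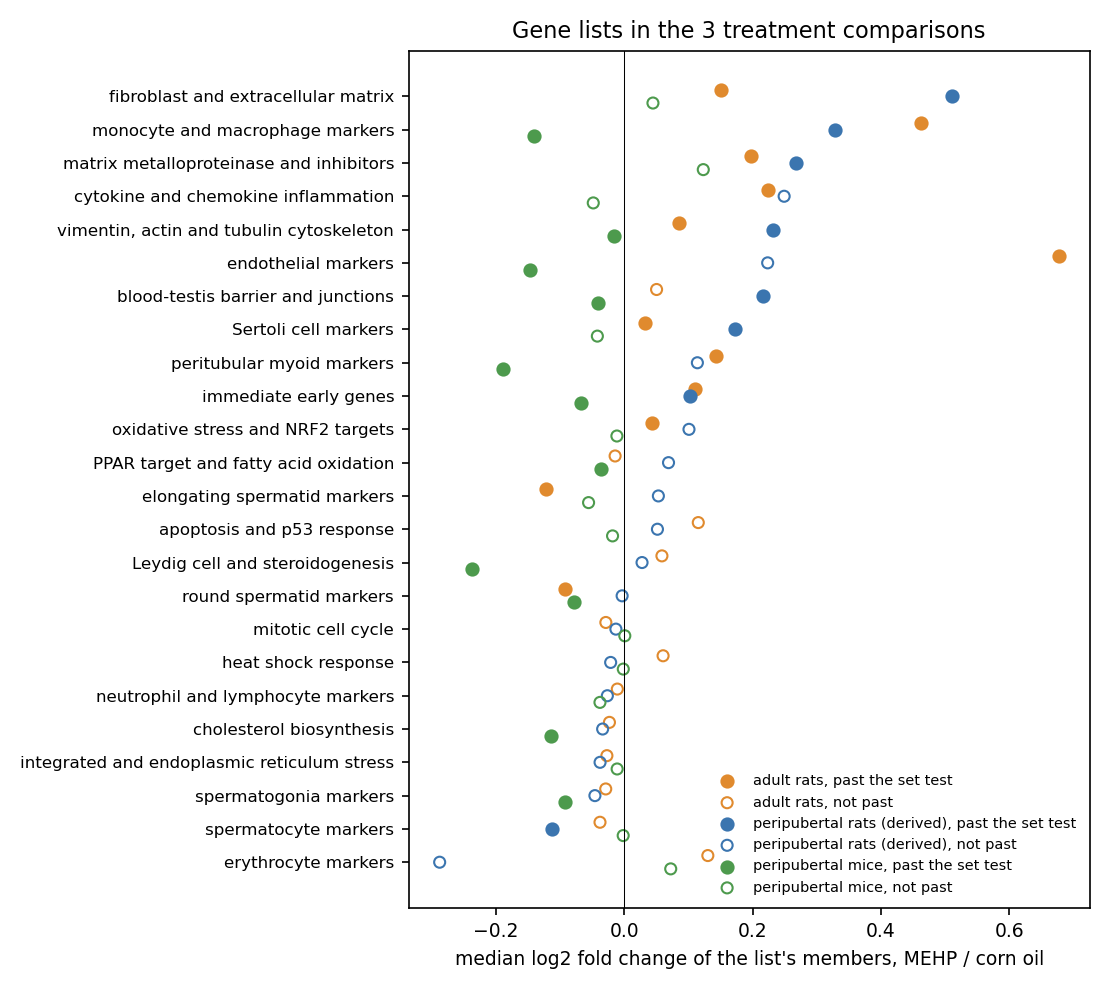
Median log2 fold change (MEHP over corn oil, x axis) of the members of each of 24 gene lists (y axis) in adult rats, peripubertal rats and peripubertal mice, with filled points for lists past the set test. The fibroblast and matrix list is at 0.15, 0.51 and 0.04, and the Leydig cell list at 0.06, 0.03 and -0.24.

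Rat and mouse responses were compared over 15467 genes paired by symbol. No gene was called in both species, where 464 were called higher in peripubertal rats and 1 in mice (Fisher exact test, two-sided, 1.0), so the overlap has almost no power to be found. Genes called higher in peripubertal rats had a median log2 fold change of 0.45 in rats and -0.01 in mice. Of 734 paired genes called in rats, 320 (43.6%) had the same sign in mice, and of all paired genes 46.8% had. The fold changes had a Spearman rho of -0.05 across genes, and -0.16 across 7427 genes with base means of at least 50 in both species. A test of the difference between the species, chosen after the data were examined, called 136 genes, 98 with a higher and 38 with a lower fold change in rats. Among them were Ctsl (difference 1.19 ± 0.15, adjusted p 6.69e-11), Serpinb1a (2.95 ± 0.45), Cdh17 (2.96 ± 0.53), Calca (4.54 ± 0.86) and Anxa2 (0.81 ± 0.17). The species were fitted separately, each with its own normalization.

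The corn-oil rats of the ages differed widely, with 6345 genes higher and 6552 lower in peripubertal than in adult testis, of 19696 tested in the authors' deposited table. Spermatid genes were lower in the younger testis. All 19 elongating spermatid markers were called lower (19 adjusted over the list alone; median -5.30, set test adjusted p 2.73e-32), including the protamine gene Prm2 (-5.74 ± 0.12), Odf1 (-5.77 ± 0.18), a sperm tail fiber gene, and Fscn3 (-7.96) in the authors' deposited table. All 18 round spermatid markers were called lower (18 adjusted over the list alone; median -2.34, adjusted p 6.01e-17), with Tssk6 at -5.61, Cst13 at -7.07 and Actl7a at -4.52 in the authors' deposited table. Sertoli cell markers (13 higher and 2 lower of 18, the same adjusted over the list alone, adjusted p 0.00596) and fibroblast and matrix genes (15 higher and 1 lower of 16, the same adjusted over the list alone, adjusted p 0.00596) stood higher. Both lost the call with a correlation of 0.05 (adjusted p 0.0529 for each).

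Among genes with a base mean of at least 10 and an established symbol, the largest differences between the ages in the authors' deposited table were in Ceacam6 (-12.13), Mlph (-10.38), Actl9b (-10.38) and Lamp3 (-10.27), lower in the younger testis, and in Cpa1 (6.55), Olr1049 (5.26), Lgals5 (4.95) and Emilin3 (4.45), higher in it. Myoid markers (8 of 10 higher, also adjusted over the list alone, adjusted p 0.0273) and spermatogonia markers (9 higher and 3 lower of 17, the same adjusted over the list alone, adjusted p 0.0273) also stood higher, and lost the call with a correlation of 0.05 (adjusted p 0.0912 and 0.109). Of 26 spermatocyte markers, 16 were called higher and 8 lower (the same adjusted over the list alone), and the set test did not pass (adjusted p 0.302). Pgk2 was at -2.58, Rec8 at -2.02 and Ldhc at -1.05 in the authors' deposited table. The mitotic list (12 higher and 8 lower of 24, the same adjusted over the list alone, adjusted p 0.245) held Mki67 at -0.87, Mcm3 at 1.66 and Ccne2 at 0.99 in the authors' deposited table.

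The authors' deposited table of GO terms gives no direction, so the sign of the median statistic of each term's genes is added here. This sign is taken against 0 and not against the other genes. In adult rats the first biological process was immune system process (1355 genes, adjusted p 2.77e-19 in the authors' deposited table). Its median was 0.0493, with 54.9% of its genes above 0, so its sign is weak. The first cellular component was extracellular space (adjusted p 1.59e-27 in the authors' deposited table). Cilium (adjusted p 6.46e-10 in the authors' deposited table) had a median statistic of -0.537. In peripubertal rats the first biological process was regulation of locomotion (1053 genes, adjusted p 9.06e-31 in the authors' deposited table). Mitochondrial protein-containing complex (235 genes, adjusted p 5.97e-17 in the authors' deposited table) had a negative median of -0.638, and actin filament binding (adjusted p 6.93e-10) a positive one of 0.471, and with the derived statistic these medians were -0.965 and 0.746. In mice, mitochondrion (1720 genes, adjusted p 7.15e-08 in the authors' deposited table) had a median of -0.141 and olfactory receptor activity (817 genes, adjusted p 1.22e-07) a median of 0.181. Of their genes, 41.9% and 59.4% were above 0. Biological processes with an adjusted p under 0.05 numbered 460 of 3806 in adult rats, 934 of 3806 in peripubertal rats and 62 of 3664 in mice, in the authors' deposited table.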

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

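The test of the difference between rats and mice, and both tests that used the larger SE of each gene, were chosen after the data were examined. The treatment effect differed between the rat ages in 17 genes by the age-by-treatment term. Among them, as peripubertal minus adult log2 fold change in the authors' deposited table, were Cdh17 (2.79), Fbxo2 (1.77), Stap2 (1.41), Sctr (1.33), Them5 (1.19), Tmem131l (0.45), Gstp1 (-0.91), Hamp (-2.57) and Wnt4 (-2.84).

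The treatment effect differed between peripubertal rats and mice in 136 genes. Among the named ones, the rat minus mouse log2 fold change was positive for Hpx (5.53), Calca (4.54), Cdh17 (2.96), Serpinb1a (2.95), Wnt4 (1.88), Cd74 (1.80), Nes (1.71), Stap2 (1.47), Lyz2 (1.32), Ctsl (1.19), Fbxo2 (1.15), Tspo (0.82), Tuba1c (0.91), Anxa2 (0.81), Tuba1b (0.61), Sparc (0.57), Mylk (0.55) and Cldn11 (0.34). It was negative for Tnp2 (-5.55), Serpina3n (-2.11) and Spata16 (-0.46). Hpx was barely detected in mice (base mean 0.654 and SE 1.42 in the authors' deposited table). Pairing by symbol assumes that equal symbols name equivalent genes.

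More genes were called in peripubertal rats (813) than in adult rats (127 with BH over the same genes). Testing the peripubertal fold changes with the adult SEs left 365 calls. By the bound set beforehand, 1.5 times the adult count, this would have argued against smaller SEs as the cause. It was set aside after it was seen, because the adult SE is below the gene's own SE in 11.5% of genes, and the reverse exchange raised the adult count to 779. With the larger SE of each gene, 167 genes were called in peripubertal and 125 in adult rats, a ratio of 1.34, so smaller SEs may account for most of the gap. The mean squared fold change beyond its squared SE was 0.0248 in peripubertal rats (bootstrap 95% interval 0.0180 to 0.0336) and 0.0136 in adult rats (0.00804 to 0.0200), over 10125 genes. The ratio of 1.83 is past the 1.5 set beforehand for a wider response. The intervals overlap, however, a condition not part of that bound, and they treat genes as independent. A mean of squares also leans on a few large changes, such as Tnp2 at -5.57 ± 1.06, and was not computed without them. A wider response at the younger age stays open.

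In mice 1 gene was called against 734 paired genes in peripubertal rats. Testing the rat fold changes with the mouse SEs gave 1592 calls, more than with their own SEs. It was set aside after it was seen, because the mouse SE is the smaller in 43.8% of genes, although by its bound of 5 calls it pointed the same way as the next test. With the larger SE of each gene, 266 genes stayed called, which argues against lower precision in the mice as the whole explanation. The mean squared fold change beyond its squared SE was -0.000765 in mice (-0.0012 to -0.000335) and 0.0191 in rats (0.0137 to 0.0284) over 7427 genes, which is consistent with a smaller response in the mouse testis at this dose and time. The value below 0 also shows mouse SEs larger than the scatter of the fold changes, as the standard deviation of the mouse statistic was 0.811. Species, housing and the separate library sets cannot be separated by this design, and neither batch nor uptake of the dose was tested.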

How the results depend on the processing

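No paired analysis was possible because values per library were not analysed here. For the same reason the planned comparison of DESeq2 with edgeR, the replicate block, leave-one-out and other splits of the libraries were not run, and whether 1 library decides a call was not tested. Tests of the difference between species and of the GO ranking were chosen after the data were examined. At an adjusted p under 0.01 the counts were 78 in adult rats, 317 in peripubertal rats, 0 in mice, 7 for the age-by-treatment term and 56 for the species difference. At 0.1 they were 1221, 40 and 297 in peripubertal rats, for the age-by-treatment term and for the species difference. With a log2 fold change of at least 1, they were 59 in adult and 67 in peripubertal rats, 7 for the age-by-treatment term and 6122 for age, and the rat ages shared 20 genes. Holm adjustment left 32, 102, 7 and 22 in adult rats, peripubertal rats, the age-by-treatment term and the species difference. A t distribution left 245 in peripubertal rats, since its tails are heavier. A base mean of at least 10 left 0 in mice. BH over all genes with a p-value is the main adjustment of the derived effect and moved no other count by over 1.5 times. With a correlation of 0.05, the lists past the test numbered 6 of 11 in mice, 0 of 5 for the age-by-treatment term and 2 of 6 for age. Ranks left 2 and a base mean of at least 10 left 1 for the age-by-treatment term. A Fisher exact test of called members passed 2 lists in adult rats, 5 in peripubertal rats, 0 in mice and 0 for the age-by-treatment term. No list past its set test changed direction under ranks or the base mean minimum. A correlation of 0.05 cannot change the direction of a list. The age difference stayed within 1.5 times of its count in all settings but the minimum fold change.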

Other observations

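The comparison of GO rankings, the naming of mouse genes and the spermatid genes compared here were chosen after the data were examined. In peripubertal rats, Tnp2 fell while 3 other genes of late spermatids did not change by as much. The implied mean level fell from 1819 to 38.2 in Tnp2, while Tnp1, the partner transition protein gene, was at 168 and 190 and Prm2 at 162 and 147. Odf1, a sperm tail gene, was at 415.1 and 472.6. In adult corn-oil rats, Tnp1 and Tnp2 had similar implied levels of 32550 and 32390, so the corn-oil level of Tnp2 in the younger rats stands above that of its partner. No value per library was analysed, so the number of animals behind this was not tested.

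The Sertoli cell and macrophage lists stood higher in peripubertal rats after MEHP, while the Leydig (adjusted p 0.665), myoid (0.291) and endothelial (0.174) lists did not pass. A lower share of germ cells would raise the markers of every somatic type alike. The medians were 0.17 for Sertoli, 0.03 for Leydig, 0.11 for myoid and 0.22 for endothelial markers, and whether they differ is not settled (permutation p 0.0989 over 100000 permutations). With a base mean of at least 10, a minimum that was not part of the prediction, the permutation p was 0.0281. Medians of the germ cell lists were -0.11 for spermatocytes, -0.05 for spermatogonia, -0.0035 for round and 0.05 for elongating spermatids, and the spermatocyte list stood lower (adjusted p 1.75e-06). The prediction needed medians below 0 in all 4 germ cell lists, and the elongating spermatid list did not meet it. All 19 of its markers were called lower in peripubertal than in adult corn-oil rats (median -5.30), as were all 18 round spermatid markers. Implied peripubertal corn-oil levels were still 162 for Prm2 and 415 for Odf1, so the age difference alone does not set its positive median aside. After MEHP, 12 elongating spermatid markers lay above 0 and 7 below, and the list did not pass the set test (adjusted p 0.645, cameraPR). A lower germ cell share is neither shown nor excluded by these values.

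Incoming macrophages are a candidate explanation for the macrophage list. Of its markers, 12.5% were called higher against 2.41% of all genes (Fisher exact p 0.0194, unadjusted, a test set beforehand). The Fisher exact test of members called in either direction, also planned, did not pass (0.0615 unadjusted, 0.184 adjusted over the 24 lists). Cd163 lost its call with the t distribution (adjusted p 0.131). A change within resident macrophages stays open.

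The authors' GO statistic for peripubertal rats equals, within rounding, the sum of the Wald statistics of the treatment and age-by-treatment terms in 9019 matched genes. This sum is not the Wald statistic of the summed effects. Its standard deviation was 0.959 over all genes, against 1.39 for the derived statistic, and in simulated unchanged genes the values were 0.742 and 0.994. It lies beyond 2, the bound behind the deposited count of changed genes per term, in 1044 genes, against 3035 for the derived statistic. With cameraPR, 26 of the 30 top terms passed with the sum and 27 with the derived statistic, and 26 passed with both. These terms were the top ones by the sum in the same data. Their passing was nearly fixed beforehand and cannot show whether the ranking matters for other terms.

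The mouse table leaves blank the name of every one of the 1425 genes listed on chromosome X, the 488 on Y and the 37 mitochondrial genes, by GENCODE M21. The genes of the authors' top mouse GO terms include 0 from chromosome X. Timp1, called in both rat ages, is among the genes left blank. It lies on chromosome X from 20870166 to 20874735 and was at 0.68 ± 0.25 in mice (adjusted p 0.997) in the authors' deposited table.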
